A study of Homo sapiens with 5 samples.

How the data were processed

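Bead array data from 5 samples of K562, an established human line from a chronic myeloid leukaemia that can be driven towards red cells or megakaryocytes, were analysed. Per the labels' protocols, cells carrying a stable, doxycycline-inducible short hairpin RNA (shRNA) were grown at 37 °C and 5% CO2 in medium with 5% serum and 0.05% antibiotics, and were given 1 µg/ml doxycycline for 48 h. Total RNA was extracted, and 0.55 µg of it was amplified into biotin-labelled cRNA and hybridised to Illumina expression beads. The labels name 3 replicates with an shRNA against JMJD1B (current symbol KDM3B, a histone H3 lysine demethylase) and 2 replicates with a control shRNA. The labels do not say whether the replicates were separate cultures, or how many shRNAs or cell clones stand behind each group. The p-values therefore measure the spread between these samples, which can be purely technical, and a difference between the stable lines cannot be separated from an effect of the knockdown.

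The values the authors deposited with sample names are bead intensity on a linear scale, and GenomeStudio 2009.2 is named in the submitters' processing notes. Settings for summarising, background and normalization are not given in the sources used here. The deposited intensity values were neither background corrected nor normalized, since no array had a signal under 109.6 and the array medians ran from 455.6 to 498.6. A further deposited table gives the same signals for 47321 probes with a detection p-value for each, per the file headers, but its 5 signal columns carry names that match no sample, so they were not used as samples. They served only as a key, and pooled over all arrays for a background level.

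The probe IDs of these deposited tables disagree. Each of the 19144 rows with sample names has 5 signals that equal those of exactly 1 probe of the larger table, yet only 47 of the rows carry that probe's ID. Probes of 1 gene were used to choose between the assignments. Over 2850 genes with 2 probes, Pearson's r between the levels of the probes (across genes, which are not independent replicates) was 0.38 under the IDs of the larger table and 0.01 under the IDs printed beside the labelled values. Of the 4 probes of EEF1A1, an abundant translation factor, 3 had mean signals of 66680 to 68183 under the former and 183 to 215 under the latter, while ILMN_3251737 had 1311 and 2155. Every row was therefore named by the ID its signals have in the larger table, and the detection p-values were attached in the same way. The sample of a value was always taken from the labelled column. Of the named probes, 14581 had 1 gene symbol in the platform annotation, 2 had several and 4561 had none. Symbols were updated through gene identifiers in a RefSeq gene table (assembly GRCh38.p14) for 14574 probes, and 7 kept the array's symbol. The named probes covered 11052 genes. The sources used here give no genome build for the array, so that table's coordinates are not printed and served only to assign genes to chromosomes and to order neighbouring genes in the closing section.

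Signals were put on a log2 scale after adding 16 and quantile normalized between arrays with limma 3.58.1 in R 4.3.3. Background correction by normexp from the detection p-values had been planned, but needs all probes of arrays with sample names. The fallback written beforehand, which skips it, was used. Fold changes are therefore on the log2(signal + 16) scale with the background still in it, and understate the change of dim genes. The pooled background was a median signal of 111.3. Probes were kept when the detection p-value was under 0.05 on at least 2 arrays, which left 19105 probes. A linear model with group as its only term (lmFit and eBayes) compared knockdown with control over all 5 arrays, with 3 residual degrees of freedom, or 10.1 with those of the prior. Benjamini-Hochberg adjusted p under 0.05 was the threshold. A gene with several kept probes was represented by the probe with the highest mean level, which gave 11041 genes. A total of 30 gene lists was tested with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), and with an estimated correlation and with fry as alternatives. The number of arrays limits the precision, with a median standard error of 0.07 on the log2 scale.

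The text names LMO2 and, per direction, the 12 genes with the largest fold change among those past the threshold whose groups did not overlap, that were detected on all arrays of the brighter group and on at least 1 of the dimmer, and whose symbol is not a placeholder. It also names up to 3 genes per direction that were undetected on all arrays of the dimmer group. Of each list it names up to 4 members past the threshold, by p, or, where no member passed, the 2 with the smallest p as values. For undetected genes the bound sets the mean of the brighter group against, per array of the dimmer group, the higher of the lowest signal with a detection p-value under 0.05 and the probe's own. The test, the lists, this rule and the alternatives listed next, except where said, were fixed before the data were examined. JMJD1B/KDM3B itself was not analysed here, because no probe named for it was among those with sample names and a symbol, so the knockdown is known from the labels alone.

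Alternatives were median scaling, cyclic loess, the deposited values without normalization, an offset of 50, no filter, a detection p-value under 0.01 on all 5 arrays, eBayes with trend and robust options, array weights, the replicate number as a block, each array left out in turn, other probes of a gene, the mean of a gene's probes, and genes in place of probes. Subtraction of the pooled background, normexp on the labelled probes alone, and the IDs printed beside the labelled values were added after seeing the data. A block for the slide was not run, because no slide is known for any array.

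The fit was tested on simulated data, with 200 of 19105 probes changed by known amounts in each of 10 simulations of knockdown against control. With spreads drawn from the fitted prior it called 36.3% of changes of 1.25-fold, 96.2% of 1.5-fold and 100% of 2-fold, and 4.33% of calls were false. With each probe's own moderated spread in place of the prior, it called 73.1%, 100% and 100% of them, and 7.53% of calls were false, above the nominal 5%. In the simulation for camera, which shifted 1 of 30 lists by 0.15 on the log2 scale, that list alone was called. This single run shifted the list of G2 and mitosis genes and drew all genes independently. It therefore does not test the preset correlation, since the correlation estimated for that list in the data was 0.12. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for joining, permutations and plots.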

Results

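Gene expression was measured on bead arrays in K562 leukaemia cells with an induced shRNA against the histone demethylase JMJD1B (3 arrays) or a control shRNA (2 arrays), after 48 h of doxycycline. The series title presents the arrays as a screen for target genes of JMJD1B and names LMO2 as a gene it activates in leukaemia. Between 18230 and 18596 of the 19144 probes with sample names were detected per array. Each of the 19144 was detected on at least 1 array, so these shares do not describe the whole array. Arrays of 1 group differed from each other by a standard deviation of 0.12 to 0.13 on the log2 scale across probes, and arrays of different groups by 0.17 to 0.18. The first principal component held 52.0% of the variance and separated the groups. JMJD1B itself was not analysed here, so the groups below are those of the labels. Fold changes are log2 differences of knockdown minus control ± standard error (n = 3 and 2), and adjusted p-values are from limma.

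LMO2, a LIM-domain adaptor of transcription complexes in blood stem cells and leukaemia, was lower in the knockdown. Its level on probe ILMN_1800078, the only probe of the gene that was measured, was 9.69 ± 0.06 (SD, n = 3) in the knockdown and 10.30 ± 0.03 (SD, n = 2) in the control. The difference of -0.60 ± 0.06, a 1.52-fold lower level, was larger than the spread between replicates (adjusted p = 0.00056). Over all 19105 probes tested, 449 were higher and 519 lower in the knockdown at an adjusted p under 0.05, or 283 and 409 of 11041 genes. Most changes were small. Only 18 probes rose and 2 fell by 2-fold or more, and 383 of the higher and 498 of the lower probes changed by less than 1.5-fold. The counts depended on every array: with any 1 of the 5 left out, 176 to 239 probes were higher and 131 to 216 lower. Of the 90 genes past the threshold that the naming rule selected besides LMO2, 52 lost the call without at least 1 array, but none of the 24 with the largest rises and falls did. The deposited values without normalization gave 723 higher and 144 lower, or 83.4% higher against 46.4% here. With the pooled background subtracted the counts were 162 and 130, and with normexp on the labelled probes alone 95 and 52. All 19144 labelled probes were detected on at least 1 array. Normexp therefore ran without the undetected probes, and is not the correction that had been planned.

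**Figure D1:**
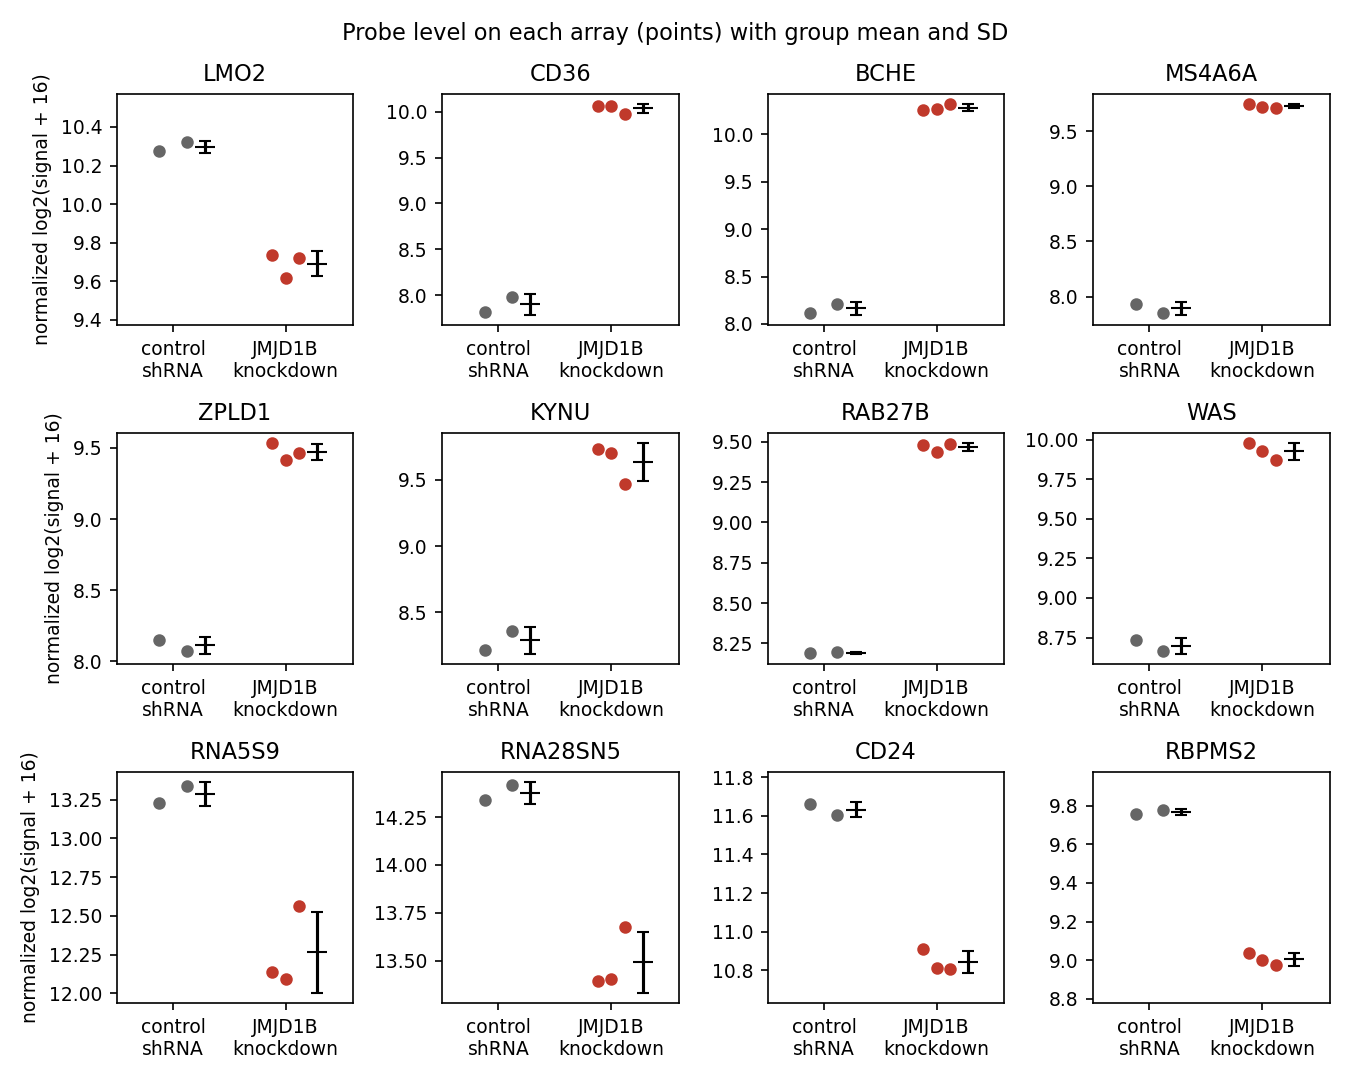
Normalized log2(signal + 16) of 12 genes on each array, with control arrays in grey and knockdown arrays in red; black marks and bars are group means and SDs (n = 2 and 3), and each panel has its own y axis. LMO2 lay at 9.69 in the knockdown and 10.30 in the control on average, and in each panel the groups do not overlap.

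The largest rises were in CD36, a scavenger and fatty acid receptor, with 2.14 ± 0.07, in BCHE, the cholinesterase of plasma, with 2.12 ± 0.06, and in MS4A6A, a membrane protein of myeloid cells, with 1.83 ± 0.06 (adjusted p = 1.5e-07 for each). CD36 is thus 4.40-fold higher on a scale that still holds the background, and its log2 difference was 2.89 after the pooled background was subtracted. Next came ZPLD1 (1.36), KYNU (1.35), a kynureninase of tryptophan breakdown, RAB27B (1.28), a GTPase of granule release, and WAS (1.23), an actin regulator of blood cells. MARCHF1, SAMSN1, TCN1, HCST and MAGEA1 rose by 1.08, 1.06, 1.03, 1.00 and 0.99. Second probes of CD36, BCHE, MS4A6A, KYNU, SAMSN1 and HCST rose by at least 0.52 of the change on the named probe. Those of RAB27B and MAGEA1 showed at most 0.22 of that change and were not called. MARCHF1 lost its call with normexp on the labelled probes alone. ABCB4, CEP192P1 and SCGB1B2P were detected in all knockdown arrays and in no control array (adjusted p = 0.014, 0.038 and 0.040). By the bound, which leaves out sampling error, they were at least 1.26-fold, 1.15-fold and 1.15-fold higher. Each of the calls was lost under some alternative.

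The largest falls were in genes for ribosomal RNA, though RNA18SN5, another such gene, was at -0.15 and was not called (adjusted p = 0.57). The signals come from amplified cRNA, and whether they follow the amount of ribosomal RNA was not tested. RNA5S9 and RNA28SN5, which encode rRNA of the large ribosomal subunit, fell by 1.02 ± 0.12 and 0.89 ± 0.09 (adjusted p = 0.0015 and 0.00039). With normexp on the labelled probes alone, their adjusted p in limma was 0.076 and 0.051. RNA5S9 had an SD of 0.26 in the knockdown and 0.08 in the control. CD24, a surface glycoprotein, fell by 0.79, the RNA-binding protein gene RBPMS2 by 0.76 and NDRG4 by 0.74. VCX, VCX3A and VCX3B fell by 0.74, 0.73 and 0.72, but these X-linked copies are near-identical and their probes may not tell them apart. BAIAP2L1 (-0.69), PRPH (-0.67), an intermediate filament protein, CDR2L (-0.66) and the receptor phosphatase PTPRF (-0.66) completed the 12. Of the 4 with a second probe, CD24 was lower by 0.38 on it, whereas RNA28SN5, VCX3A and PTPRF were at -0.38, -0.28 and -0.21 on theirs and lost the call. FCGBP, ACVRL1 and PITPNC1 were detected in both control arrays and in no knockdown array (adjusted p = 0.011, 0.042 and 0.024). By the same bound they were at least 1.22-fold, 1.14-fold and 1.14-fold lower, and each of these calls too was lost under some alternative.

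Of the 30 gene lists, 4 were called by camera with a preset correlation, all towards higher levels, and none of them held with an estimated correlation. That alternative rests on the 3 residual degrees of freedom, so it has little power and its failure decides little. The estimates were 0.12 for G2 and mitosis and for oxidative phosphorylation, 0.05 for histone and -0.04 for cancer-testis genes, against the preset 0.01. Among the members named below, ZWINT, CD247, SOD2, PHLDA1, GCLM, HK2, VEGFA and SREBF1 lost the call on the next probe of the gene, without a change of sign. The same held for RAB27B and MAGEA1, whose second probes are given above. Genes of G2 and mitosis were the clearest. Of 45 measured, 41 had positive differences with a median of 0.16, 6 rose over all probes tested and 15 adjusted over the list alone (camera adjusted p = 1.1e-10, but adjusted p = 0.59 with an estimated correlation). AURKB, a kinase of chromosome segregation, rose by 0.48, the kinetochore genes NDC80 and ZWINT by 0.32 and 0.31, and the checkpoint kinase BUB1 by 0.25, though each of these calls was lost without at least 1 array. Replication-dependent histone genes had a median of 0.08, with 5 of 42 higher and 1 lower over all probes and 12 and 1 adjusted over the list alone (camera adjusted p = 0.00086, and adjusted p = 0.59 with an estimated correlation). H2BC21 (0.36), H4C12 (0.29) and H1-4 (0.35) rose, and H2BC5 fell by 0.31 on its named probe while its next probe was at 0.002. S-phase genes had 0 of 38 members past the threshold in limma, 0 adjusted over the list alone, and a median of 0.02; PRIM1 (0.26) and MCM7 (0.18) had the smallest p-values.

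Oxidative phosphorylation subunits and cancer-testis genes passed narrowly (camera adjusted p = 0.049 for each, and adjusted p = 0.67 and 0.59 with an estimated correlation). In the former, 1 of 69 genes rose, ATP5MC1 with 0.26, whose next probe was at -0.02, 0 passed adjusted over the list alone, and the median was 0.05. In the latter, 4 of 16 rose and 1 fell, or 5 and 1 adjusted over the list alone, and the median was only 0.02. MAGEA1 rose as given above, the X-linked genes MAGEB2 and SPANXA1 by 0.63 and 0.67, and SPANXB1 by 0.41; SPANX copies are near-identical.

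**Figure D2:**
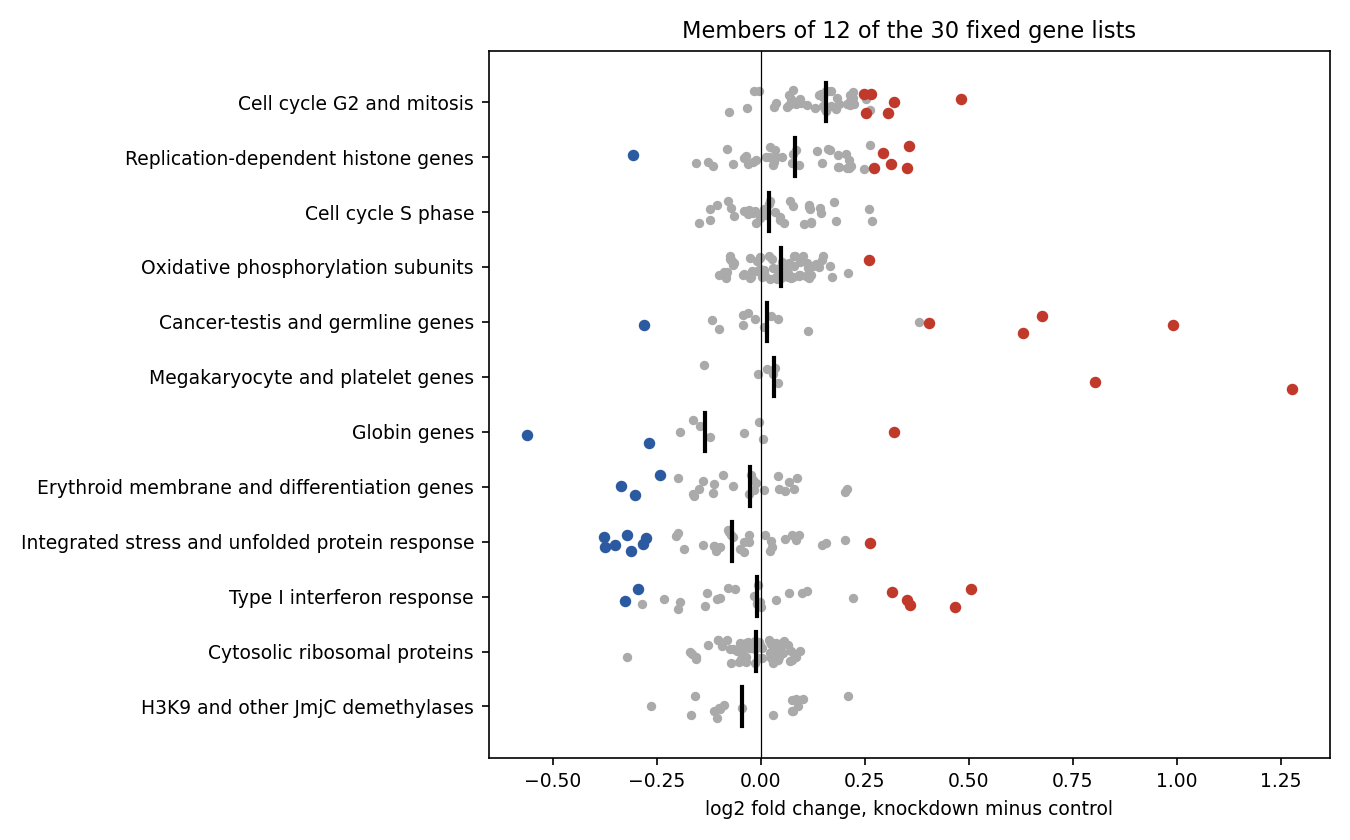
Log2 fold change (x axis, knockdown minus control) of each measured member of 12 of the 30 gene lists, with members past adjusted p 0.05 in red (higher) or blue (lower), others in grey, and the list median as a black bar. The bar of the G2 and mitosis list stands at 0.16, and that of the ribosomal protein list at -0.01.

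No list of a blood lineage was called by camera, though single members changed. Among LMO2 partners and stem cell regulators, 2 of 28 rose (4 higher and 2 lower adjusted over the list alone), namely the transcription factors MYB by 0.30 and GFI1B by 0.33 (camera adjusted p = 0.22). Of 8 megakaryocyte and platelet genes, 2 rose (also 2 adjusted over the list alone), RAB27B and the integrin ITGA2B, the latter by 0.80 ± 0.10 (camera adjusted p = 0.11). Of 10 globin genes and their chaperone, 1 rose and 2 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.20): embryonic HBZ fell by 0.56, HBQ1 by 0.27, and HBD rose by 0.32. In haem synthesis and iron handling 1 of 20 fell, ALAS2, the first enzyme of erythroid haem synthesis, by 0.51 (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.35). In the erythroid membrane list 3 of 26 fell (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.36), the glucose transporter SLC2A1 by 0.33, and the blood group genes XK and RHCE by 0.30 and 0.24.

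Of myeloid and monocyte genes, 2 of 12 rose, MS4A3 by 0.69 and the Fc receptor FCGR2A by 0.39 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.43). Of lymphocyte genes, 2 of 11 rose and 1 fell, PRF1 (0.63), CD3D (0.38) and CD247 (-0.40), with 3 and 1 adjusted over the list alone (camera adjusted p = 0.32). Type I interferon genes moved both ways, with 5 of 28 higher and 2 lower (5 and 6 adjusted over the list alone; median -0.01, mean 0.01, camera adjusted p = 0.89 towards higher): CXCL10, IFIT1 and ISG15 rose by 0.51, 0.47 and 0.36, and ISG20 fell by 0.30. Of 15 NF-kB and inflammatory genes 2 rose, NFKBIZ by 0.51 and SOD2 by 0.33, and RELB fell by 0.30 (3 and 3 adjusted over the list alone; camera adjusted p = 0.59). Of 9 MHC genes 1 fell, HLA-B by 0.30 (also 1 adjusted over the list alone; camera adjusted p = 0.43). Of 6 genes of epithelium, fibroblasts and endothelium, ESAM rose by 0.44 and EPCAM fell by 0.51 (1 and 1 adjusted over the list alone; camera adjusted p = 0.84).

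Among 36 genes of the integrated stress and unfolded protein responses, 1 rose and 7 fell (2 and 9 adjusted over the list alone), though the list was not called (camera adjusted p = 0.12). The stress regulators DDIT3, TRIB3 and CEBPB fell by 0.37, 0.38 and 0.31, and the chaperone HSPA5 by 0.32. Of 21 heat shock genes 3 fell, BAG3 by 0.33, CRYAB by 0.39 and FKBP4 by 0.30 (4 adjusted over the list alone; camera adjusted p = 0.51). Immediate early genes had 3 of 28 higher and 1 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.94). JUN, PHLDA1 and KLF6 rose by 0.34, 0.27 and 0.25, and ATF3 fell by 0.56 on its named probe while its next probe was at 0.05. In the metallothionein and oxidative stress list 2 of 25 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.43), namely MT2A (-0.44), GCLM (-0.38), the zinc exporter SLC30A1 (0.35) and the cystine transporter SLC7A11 (0.26). Of 35 genes of glycolysis and hypoxia 3 fell, SLC2A1, HK2 by 0.31 and VEGFA by 0.27 (also 3 adjusted over the list alone; camera adjusted p = 0.57). MSMO1, of sterol synthesis, fell by 0.42 and SREBF1 rose by 0.25, the only called members of 27 (2 and 2 adjusted over the list alone, camera adjusted p = 0.38). Of the 2 other kept probes of MSMO1, only 1 was lower as well, and it was called. HRK, a pro-apoptotic gene, fell by 0.47 as the only 1 of 23 apoptosis regulators (also 1 adjusted over the list alone; median and mean -0.01, camera adjusted p = 0.89 towards higher), and XPC, of DNA repair, by 0.44 as the only 1 of 20 p53 targets (2 higher and 5 lower adjusted over the list alone; median 0.03, mean -0.04, camera adjusted p = 0.83 towards lower).

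The chromatin lists had no member past the threshold in limma, over all probes or adjusted over the list alone. Among 17 other JmjC and lysine demethylases, KDM6B (-0.26) and KDM2B (-0.16) had the smallest p-values (camera adjusted p = 0.84), and among 16 H3K9 methyltransferases and heterochromatin proteins EHMT2 (0.14) and SETDB2 (-0.13) did (camera adjusted p = 0.66). Cytosolic ribosomal proteins had 0 of 67 called, with a median of -0.01 and with RPL28 at -0.17 and RPS23 at -0.15 (camera adjusted p = 0.89). Several of their probes, such as RPS12 with a mean level of 16.04 in the knockdown and RPL32 with 16.01, lay near the highest signals of the arrays. A change may not show there. Ribosome biogenesis and MYC targets had 0 of 36, with LYAR at -0.23 and POLR1C at -0.28 (camera adjusted p = 0.36). At an unadjusted p under 0.05, 4042 of all 19105 probes passed. Proteasome subunits had 1 of 32 higher, PSMD8 by 0.30 (also 1 adjusted over the list alone; camera adjusted p = 0.19), and mitochondrial ribosome genes 1 of 79, MRPL41 by 0.24 (0 adjusted over the list alone; camera adjusted p = 0.43).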

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

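Both tests of the probe IDs were chosen after the mismatch had been seen. Probe ILMN_1762678 was detected on all 5 arrays of the larger table, where its lowest signal was 881 against a pooled background of 111.3, but its signals are not among the rows with sample names. It was the only such probe among the 28177 outside those rows, of which 24817 were detected on no array. It entered no comparison, since its signals carry no sample name. Groups of 3 and 2 arrays are too small for a test of single outlying arrays.

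Beside the labelled signals, 19143 of the correct probe IDs were present but in another order. The tables argue against the larger table being the misplaced one: levels of probe pairs of 1 gene were correlated more strongly under its IDs, by 0.38 in Pearson's r across genes. A candidate explanation is that signals and IDs of the labelled table were each sorted by fold change on slightly different values. Spearman's rho between the fold change of a row and that of the probe printed beside it was 0.99 across 19065 rows, while rho of mean levels was 0.02. Of 87 rows changed by 1.5-fold or more, 26 stood beside the ID of a probe that changed in the opposite direction. The ID of RNA5S9 (-1.02), for example, stood beside values with a difference of 0.99. Slightly different values would not give this, so the explanation falls short for these rows. No biological explanation was tested.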

How the results depend on the processing

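Subtraction of the pooled background, normexp and the IDs printed beside the labelled values were chosen after seeing the data. LMO2 kept its direction and its side of the threshold under the 16 alternatives that use its own probe, between -0.55 and -0.70 with adjusted p from 3.7e-05 to 0.038, and between -0.63 and -0.57 with any 1 array left out. The printed IDs mostly follow the order of fold changes and give LMO2 another probe's value (-0.56, of NUPR1), which is no support. No second probe of LMO2 was kept, JMJD1B has no value under any alternative, and a block for the slide was not run. The numbers of probes higher and lower stayed within 1.5 times the reported 449 and 519 under median scaling, cyclic loess, an offset of 50, no filter, the stricter filter, array weights, eBayes with trend and robust options (657 and 747), and with genes fitted in place of probes (403 and 598). They did not with the deposited values without normalization (723 and 144, or 83.4% higher against the reported 46.4%, with the median of all probes at 0.08), with the pooled background subtracted (162 and 130) or with normexp (95 and 52, or 64.6% higher); the cause was not tested. Of these calls, 593, 282 and 137 were shared with the reported ones in the same direction and 0 were opposite. Leaving out 1 array, which leaves fewer samples, gave 176 to 239 higher and 131 to 216 lower: 239 and 215 without knockdown replicate 1, 197 and 164 without 2, 238 and 216 without 3, 196 and 134 without control replicate 1, and 176 and 131 without 2. A lone control was assumed to vary like the knockdown arrays.

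The labels name no pairing of the samples. Deviations from the group means of same-numbered arrays had r = -0.22 and -0.09 across probes. With 2 control arrays their deviations are mirror images, so the same knockdown arrays had r = 0.22 and 0.09 with the other control. These values therefore cannot decide whether the replicate numbers pair the samples. With the replicate block 194 probes were higher and 145 lower, 2 lists were called, and the median of the cancer-testis list was -0.013.

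Camera called 4 lists, and 2 to 4 with any 1 array left out. With an estimated correlation 0 were called, with fry 2 (cancer-testis and megakaryocyte genes), and 2 each with the stricter filter, the mean of a gene's probes, the pooled background subtracted, normexp and the IDs printed beside the labelled values; the cause was not tested. Over the alternatives, adjusted p of the G2 and mitosis list ran from 3.0e-11 to 0.59, of the histone list from 6.8e-05 to 0.59, of oxidative phosphorylation from 0.0036 to 0.67 and of the cancer-testis list from 0.0059 to 0.59. With 1 array left out, the cancer-testis median ran from -0.012 (knockdown replicate 3) to 0.068 (control replicate 2). On the next probe of the gene, ATF3 (0.046), ATP5MC1 (-0.024) and H2BC5 (0.0020) changed sign, and of the other 31 values, 18 stayed on their side of the threshold and 13 lost the call. Under the IDs printed beside the labelled values, RNA5S9 (0.99), RNA28SN5 (1.03), VCX (1.06), VCX3A (0.99), VCX3B (1.09) and MT2A (1.23) turned positive. Of the 90 named genes with a call besides LMO2, 32 to 44 lost the call without 1 array, 59 lost the call with normexp, 47 with the pooled background subtracted and 20 without normalization, in the same direction. Background limits dim genes.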

Other observations

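All tests in this part were chosen after the result was seen. Structural RNAs went apart. Of 12 genes for rRNA, 7SK, U1, U6 and U3 RNA, 8 were called lower in the knockdown. The median log2 difference of the 12 was -0.45, and -0.37 in the deposited values without normalization. RNA18SN5 (-0.15) and the U3 genes SNORD3A, SNORD3C and SNORD3D (-0.12 to -0.29) were not called. The calls include the U1 copies RNU1-1, RNU1-3, RNVU1-7 and RNVU1-18, whose probes may not tell them apart. A further 12, short RNAs without a poly(A) tail such as RN7SL1, RMRP and Y RNAs, had a median of 0.005, with RNU11 higher by 0.53 (adjusted p = 0.015) and 0 lower in limma. Of 120 small nucleolar RNAs, 8 were higher and 0 lower, with a median of 0.07. These sets were chosen after their values were seen. Whether signals from amplified cRNA follow the amount of such RNAs was not tested.

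Several of the largest rises were in genes usually read in leukocytes, such as CD36, MS4A6A, WAS and HCST. Of 22 genes abundant in leukocytes, listed after the rises were seen, 9 were measured and none was called, with LYZ at -0.22, CD14 at -0.14, LSP1 at -0.11, CD79A at -0.04, HLA-DRA at 0.004, AIF1 and CD37 at 0.02, CORO1A at 0.20 and the brightest, CD52, at 0.30. Their median was 0.0041, but members go both ways, and the list leaves out leukocyte genes that rose, among them ARHGDIB (0.97), CD69 (0.92), LAPTM5 (0.81), HCLS1 (0.74) and IL2RB (0.65), so it does not exclude an admixture. Cross-hybridisation of the named probe is argued against for CD36, BCHE, MS4A6A, KYNU, SAMSN1 and HCST, whose second probes showed at least 0.52 of the change, but may account for RAB27B and MAGEA1, where the ratio was at most 0.22. An admixture, a response to the knockdown and a lasting difference between the stable lines remain open.

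Genes of chromosome 15 were lower in the knockdown relative to other genes. Over 348 genes the median log2 difference was -0.07, 74.1% of them were negative against 52.5% elsewhere, and 31 were called lower and 2 higher, RBPMS2 (-0.76) and ISG20 (-0.30) among the lower; without normalization their median was -0.004 and that of the other chromosomes 0.07. Chance placement of genes is argued against by a permutation p of 0.0001, the smallest that 10000 draws can give, or 0.0023 adjusted over 23 chromosomes, though neighbouring genes are not independent, and chromosomes 14, 11, 2, 16 and 20 also passed with medians between -0.03 and 0.01. A difference of 1 copy in 4 or fewer between all cells of the lines would give -0.42 or beyond if signals followed copy number in full, which was not tested. Even in the lowest window of 50 neighbours, from ZFYVE19 to AFG2B, the 21 bright genes had a median of -0.13 ± 0.03 (bootstrap SE). That window was no lower than chance orders of the chromosome's own genes give (one-sided permutation p = 0.419), so no block was found, and a copy number difference in part of the cells of 1 line and a response to the knockdown both remain open.

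Neighbouring genes were called in the same direction more often than in permuted orders, in 35 pairs against a mean of 22.3 (one-sided permutation p = 0.0067 over 11024 genes), among them TCN1, MS4A3, MS4A6A and MS4A4A, and IFIT2, IFIT3 and IFIT1. The hypothesis that neighbours of 1 gene family make up this excess was tested by leaving out neighbours whose symbols share their first 3 letters. The remaining 21 pairs compare with 21.2 expected (one-sided permutation p = 0.547), which is consistent with it.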
